A study of Mus musculus with 11 samples.

How the data were processed

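Bulk RNA sequencing covered 9 libraries of sorted mouse liver cells and single-cell RNA sequencing covered 2 libraries of liver cells from metastasis-bearing mice. The deposited bulk values were TPM per gene. The authors' processing notes list kallisto 0.44.0, which estimates TPM by pseudoalignment, and bcl2fastq 2.19, DESeq2 and Cell Ranger without saying which step used which, with the builds GRCm38 and mm10. The deposited single-cell values were UMI counts per gene and cell barcode, made with Cell Ranger 3.1.0 per the file headers and not normalized. Per the labels, bulk CAF were sorted after a density gradient as double-positive cells for Col1a1-GFP and TdTomato, and quiescent HSC on retinoid fluorescence and/or TdTomato from a strain without the collagen reporter. The single-cell suspensions took an extra trypsin digestion, and Chromium 3′ v3 chemistry was used for them.

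Groups followed the sample titles. For the single-cell libraries the titles name Panc02 and CMT93, while the descriptions of the same samples name models of intrahepatic cholangiocarcinoma (YAP/AKT and KRAS/P19). The titles, which the file names share, were followed, and every single-cell statement about a tumour model depends on that choice. Bulk replicates were numbered in accession order. No paired analysis was possible because those numbers carry no pairing between groups.

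The bulk table held 35240 entries, of which 26 had date-like names from spreadsheet conversion (19 of them tested under those names) and 2 were duplicated names. Genes with at least 1 TPM in at least 2 libraries were kept (14217). Values were log2(TPM + 1). A linear model with 1 mean per group was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3) with an intensity trend in the empirical Bayes step (prior degrees of freedom 3.80, residual degrees of freedom 5). The CAF arm against HSC was the mean of the 3 CAF group means. The HSC group of 1 library was assumed to vary like the CAF groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. These p-values are approximate, since TPM carry no count-based weights.

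Gene lists, 31 with 477 genes in all, were written before the data were examined, as were the comparisons, the thresholds for calling genes and the alternatives, except where stated otherwise. Lists with at least 3 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry. Members were also adjusted over the list alone. Named genes followed a fixed rule. It took the 10 called genes with the largest rise and the 10 with the largest fall, among genes with a mean of at least 10 TPM in the higher group and every library of the higher group above every library of the lower, together with 10 always-named genes and the 2 to 4 members of each described list with the smallest p. Mitochondrial, ribosomal protein, pseudogene and provisional symbols were skipped. In single cells it took the 10 genes with the highest and the 10 with the lowest ratio, outside the naming markers.

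For single cells, barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, genes in at least 3 cells were used, and doublets called by scrublet were removed. Filtering removed 302 of 5039 barcodes in Panc02 and 85 of 6156 in CMT93, and scrublet called 3 doublets (0.0633%) and 169 (2.78%), so doublets may remain in the Panc02 library. Each library was processed on its own in scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9) with a scale total of 10000, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 and seed 1. A marker counted as on in a cluster at 20 CPM or more, at 20% or more of its highest cluster and in 10% or more of cells. A cluster took the class with the largest share of its markers on, at least 3. It stayed unnamed if a rival class had at least 3 and 50% or more of its markers on and 50% or more of the leader's share, if its top 10 genes held more markers of another class, if its cells were shallow with no marker in that top 10, or if it was not fibroblast-like and had nearly all markers of a fibroblast sub-class on. Fibroblast and smooth muscle classes did not count as rivals. A fibroblast-like cluster got no sub-class when under 3 sub-class markers were on or its top 10 genes held more markers of another sub-class. These naming thresholds and the rule for leaving a cluster without a sub-class were set after seeing the data.

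UMIs were summed over each class, with exact Poisson intervals for CPM and Clopper-Pearson intervals for shares (95%). A share of 0 allows up to 3 counts in the cells examined, which is 0.0634% of all Panc02 cells and 0.0508% of all CMT93 cells. Shares of cells with a UMI were repeated after thinning each cell to 2000 UMIs, for which 29 Panc02 and 42 CMT93 fibroblast-like cells were too shallow. Log2 ratios added 1 CPM to each side, and genes at 50 CPM or more in the higher library could be named. The median ratio of a list was placed among 10000 random lists matched in 20 expression bins (genes at 5 CPM or more). Numerical work used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

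The bulk test was tested on simulated data with 200 of 14217 genes changed. Of 100 genes changed by a log2 of 1 and of 100 changed by 2, it recovered 38 and 81 for CAF against HSC, 40 and 87 for Panc02 against CMT93, 43 and 82 for KPCY against CMT93, and 57 and 91 for Panc02 against KPCY. It called 5, 12, 12 and 11 unchanged genes. Most changes of 2-fold were thus missed in 3 of the 4 simulated comparisons. The Benjamini-Hochberg cutoff is less strict where many more genes change. The data had 6044 calls in CAF against HSC and 2582 in KPCY against CMT93, so these recovery rates do not carry over directly. In simulated single-cell sums with a log2 change of 1 in either direction, the median estimates were 0.98 and -0.95, and 94.7% of the true means lay in the Poisson interval. An unchanged list fell at percentile 95.1, so single percentiles of that size carry little weight.

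Alternatives tried in bulk were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 TPM, median-ratio and quantile scaling, empirical Bayes without trend and robust, each CAF library of a comparison left out in turn, fits of 2 groups alone, and the CAF arm as the mean of 8 libraries. The HSC library was never left out. Those for single cells were 200 and 1000 genes per cell, 10% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, thinning, the mean of per-cell CPM, and CPM without the 20 most abundant genes. Chosen after seeing the data were the analysis with unnamed clusters led by fibroblast markers, the analysis within each sub-class, and the bulk comparisons without immunoglobulin, T-cell receptor and pancreatic acinar genes.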

Results

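Gene expression was measured in hepatic stellate cells (HSC), the vitamin A-storing pericytes of the liver, and in the cancer-associated fibroblasts (CAF) that descend from them in mouse liver metastases. Bulk RNA sequencing covered 9 libraries. Quiescent HSC from an undamaged liver gave 1 library. CAF came from metastases seeded by splenic injection of 3 tumour lines, with 3 libraries for Panc02 (pancreatic), 3 for KPCY (pancreatic) and 2 for CMT93 (colorectal). The sorted CAF carried both the Col1a1-GFP collagen reporter and the Lrat-Cre TdTomato label of the stellate lineage. Single-cell RNA sequencing covered 1 library of CAF-enriched liver cells for Panc02 and 1 for CMT93. The series labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

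The bulk values were TPM, transcript abundances scaled to the same total in each library, so read depth is unknown. Genes at 1 TPM or more numbered 12383 in the HSC library and between 13042 and 13295 in the CAF libraries. The 20 most abundant genes took 19.3% of all TPM in HSC and 12.6% to 16.4% in CAF. Ecm1, a secreted matrix protein of quiescent stellate cells, was the most abundant transcript in HSC at 27459 TPM, and Col3a1, a fibrillar collagen chain, was the most abundant in every CAF library (15737 to 23810 TPM). Across genes, replicates of a group correlated with r between 0.962 and 0.984, and no pair of libraries held identical values. Correlation of HSC with KPCY CAF libraries was 0.844 to 0.850, against 0.798 to 0.822 with Panc02 CAF and 0.806 to 0.809 with CMT93 CAF. In a principal component analysis of all 9 libraries, the first component (52.2% of variance) separated HSC from CAF and the second (18.6%) separated KPCY from the other libraries. The single-cell libraries held 5039 barcodes with 55964952 unique molecular identifiers (UMIs) for Panc02 and 6156 barcodes with 63615536 UMIs for CMT93. Median UMIs per barcode were 8505 and 7903.

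The comparison of CAF with quiescent HSC asked how stellate cells change when they become fibroblasts of a metastasis. The CAF mean TPM below is over 8 libraries, and fold changes are on the log2(TPM + 1) scale with standard errors (SE) from limma. Mgp, which encodes the calcification inhibitor matrix Gla protein, rose most, from 1.04 to 2161 TPM (log2 fold change 9.86 ± 0.28, adjusted p = 5.25e-08). S100a6, Spp1 (osteopontin), Mfap4, Sfrp1, Col15a1, Aldh1a2, Serpinf1, Dpt and Col12a1 followed, with log2 fold changes from 9.05 to 7.69. The largest fall was of Fcna, a ficolin of innate immunity, from 4857 to 32.5 TPM (log2 fold change -8.13 ± 1.00, adjusted p = 0.000245). Angptl6, Tmem56, Clec4g, Colec10, Dnase1l3, Mup19, Mapt, Bmp10 and Vipr1 also fell, by 6.91 to 5.71 on the log2 scale. Clec4g and Dnase1l3 were also leading genes of an endothelial-like single-cell cluster (CMT93 cluster 6), and the endothelial and hepatocyte lists fell as well (below). Whether RNA of other cells in the HSC library contributed to these falls was not tested.

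The mediators at the centre of the study moved in different directions between HSC and CAF. Col1a1 and Col1a2, the chains of type I collagen, rose by 7.36 ± 0.18 (adjusted p = 2.99e-08) and 4.58 ± 0.17 (adjusted p = 3.21e-07). Col1a1 lies on chromosome 11 at 94936224 to 94953042 and Col1a2 on chromosome 6 at 4504814 to 4541544 (GRCm38). Has2 (chromosome 15, 56665627 to 56694539), a hyaluronan synthase, rose from 0.0566 to 35.3 TPM (4.84 ± 0.38, adjusted p = 2.04e-05), and Cd44, a hyaluronan receptor, rose by 2.89 ± 0.14 (adjusted p = 1.18e-06). Hgf (chromosome 5, 16553495 to 16620152), the ligand of the receptor Met, fell from 1268 to 112 TPM (-4.01 ± 0.38, adjusted p = 6.17e-05). Lrat, the enzyme that esterifies retinol for storage, fell by 4.22 ± 0.58 (adjusted p = 0.000466), and the chemokine gene Cxcl12 fell by 2.82 ± 0.50 (adjusted p = 0.00199). Acta2 (smooth muscle actin) and Timp1 (a metalloproteinase inhibitor) rose by 7.65 ± 0.18 and 6.82 ± 0.17, each with adjusted p = 2.99e-08. The cytokine Il6 rose by 3.85 ± 0.74 (adjusted p = 0.00305).

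**Figure D1:**
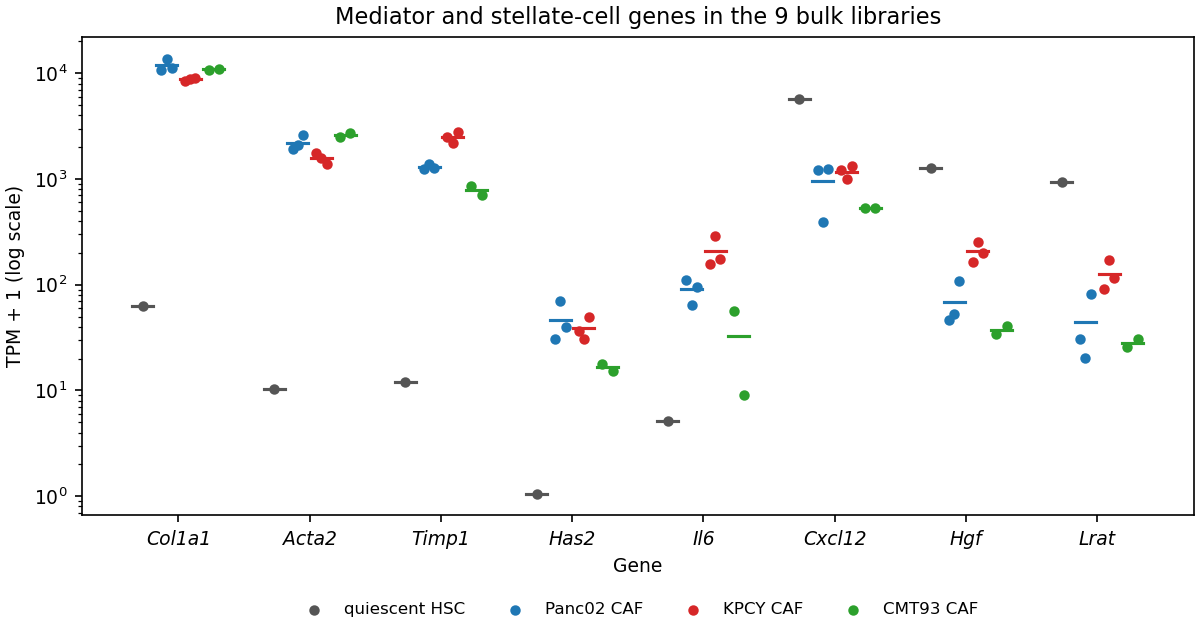
TPM + 1 of 8 mediator and stellate cell genes in each bulk library on a log axis, with points for libraries and lines for group means of HSC (1 library), Panc02 CAF (3), KPCY CAF (3) and CMT93 CAF (2). Has2 stood at 0.0566 TPM in HSC and at 14.4 TPM or more in every CAF library, whereas Hgf stood at 1268 TPM in HSC and at 252 TPM or less in CAF.

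Among gene lists fixed beforehand, 18 of 22 quiescent stellate cell genes fell and 0 rose (median log2 fold change -4.15, camera adjusted p = 1.88e-10, adjusted p = 0.297 with an estimated correlation), led by Rspo3 (-4.10 ± 0.21) and Ecm1 (-4.73 ± 0.29). The contractile list had 17 of 20 members up and 0 down (camera adjusted p = 7.94e-11, adjusted p = 0.128 with an estimated correlation), with Cthrc1 at 7.63 ± 0.19, Thy1 at 7.55 ± 0.19 and Tnc at 4.40 ± 0.13. Of 22 fibrillar collagen and matrix genes 20 rose and 1 fell (camera adjusted p = 9.79e-11, adjusted p = 0.170 with an estimated correlation), among them Fbln2 (7.31 ± 0.15) and Col5a2 (4.72 ± 0.17). Collagen crosslinking genes rose in 19 of 24 cases and fell in 1 (camera adjusted p = 1.15e-07, adjusted p = 0.128 with an estimated correlation), with the lysyl oxidases Lox (6.43 ± 0.21), Loxl1 (3.42 ± 0.15) and Loxl2 (2.40 ± 0.12). Basement membrane genes rose in 10 of 14 cases and fell in 1 (camera adjusted p = 0.00297, adjusted p = 0.226 with an estimated correlation). Proliferation genes rose in 21 of 24 cases and none fell (camera adjusted p = 1.88e-10, adjusted p = 0.297 with an estimated correlation), for example the kinase gene Aurkb (3.41 ± 0.18) and the cyclin gene Ccna2 (2.97 ± 0.18). Hypoxia and glycolysis genes rose in 14 of 19 cases and fell in 1 (camera adjusted p = 0.0002, adjusted p = 0.243 with an estimated correlation).

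Inflammatory fibroblast genes rose in 14 of 24 cases and fell in 4 (camera adjusted p = 0.00269, adjusted p = 0.337 with an estimated correlation), led by Svep1 (5.31 ± 0.15), Dpt, Lcn2 (3.93 ± 0.23) and complement C3 (6.00 ± 0.37). Interferon response genes moved the other way, with 19 of 22 down and 0 up (camera adjusted p = 1.81e-09, adjusted p = 0.226 with an estimated correlation), among them Gbp3 (-1.45 ± 0.14) and Irf7 (-1.81 ± 0.20). Class II antigen presentation genes rose in 6 of 10 cases with none down (camera adjusted p = 0.0413, adjusted p = 0.467 with an estimated correlation). Hyaluronan genes were split, 8 up and 4 down of 14 (camera adjusted p = 0.233), with the scavenger receptor Stab2 at -4.91 ± 0.38. Stab2 was also a leading gene of the endothelial-like CMT93 cluster 6. Growth factor genes rose in 15 of 34 cases and fell in 6 (camera adjusted p = 0.135), with Igf1 at 4.73 ± 0.19 and Tgfb2 at 4.12 ± 0.19. In the retinoid list 3 of 14 rose and 5 fell (camera adjusted p = 0.233, median -0.23 but mean 0.17), where Aldh1a2, a retinaldehyde dehydrogenase, rose by 7.93 ± 0.20 and Plin2, a lipid droplet protein, fell by 1.54 ± 0.12. For YAP targets 4 of 15 rose and 7 fell (camera direction down with adjusted p = 0.595, median 0.12). Both the retinoid and the YAP list had an upward balance by fry, with adjusted p = 0.0256 and 0.0347. Adjusted over the list alone, the counts up and down stayed the same for all of these lists except basement membrane (10 and 2), proliferation (22 and 0), hypoxia (15 and 1), inflammatory (17 and 4), YAP (5 and 7) and retinoid (4 and 5).

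Markers of other cell types also differed between HSC and CAF. All 12 portal fibroblast genes and all 10 mesothelial genes rose in CAF (camera adjusted p = 3.79e-08 and 9.25e-05, adjusted p = 0.226 and 0.313 with an estimated correlation), among them Mfap4 (8.43 ± 0.20) and Msln (5.24 ± 0.54). Smooth muscle genes rose in 7 of 10 cases and fell in 2, and tumour epithelial genes rose in 6 of 9 cases with none down (camera adjusted p = 0.0413 and 0.0137, adjusted p = 0.423 and 0.426 with an estimated correlation). Endothelial genes fell in 12 of 13 cases with none up, including Kdr (-4.40 ± 0.35), and hepatocyte genes fell in 11 of 17 cases with 2 up (camera adjusted p = 6.53e-08 and 0.00184, adjusted p = 0.246 and 0.423 with an estimated correlation). Immediate early genes, which respond to cell isolation, fell in 11 of 14 cases with none up (median -2.02), and mitochondrially encoded genes fell in 2 of 13 (camera adjusted p = 0.000139 and 0.0318, adjusted p = 0.423 and 0.567 with an estimated correlation). Adjusted over the list alone, 0 mitochondrially encoded genes, 12 hepatocyte genes and 3 smooth muscle genes fell, and 1 T and NK cell gene rose. Counts up and down were 2 and 4 of 17 for macrophages, 2 and 0 of 8 for T and NK cells, 1 and 0 of 4 for B and plasma cells and 4 and 1 of 7 for neutrophils. They were 3 and 2 of 7 for dendritic cells, 0 and 1 of 3 for mast cells, 1 and 2 of 3 for platelets and 0 and 0 of 5 for erythroid genes, and no camera call was made for these lists. The lowest unadjusted camera p among them was 0.0632, for macrophages. Only 2 intestinal epithelial genes entered the test, and Lgals4 fell by 1.56 ± 0.46 (adjusted p = 0.0232).

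In total 3714 of 14217 genes rose and 2330 fell in CAF against HSC at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Under median-ratio scaling the split was 3338 up and 2933 down, and under quantile scaling it was 2971 and 3018, with the median log2 fold change of all genes moving from 0.13 to -0.03. The HSC arm had 1 library and was assumed to vary like the CAF groups, and the mouse strain and any batch of that library cannot be told apart from the cell state.

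**Figure D2:**
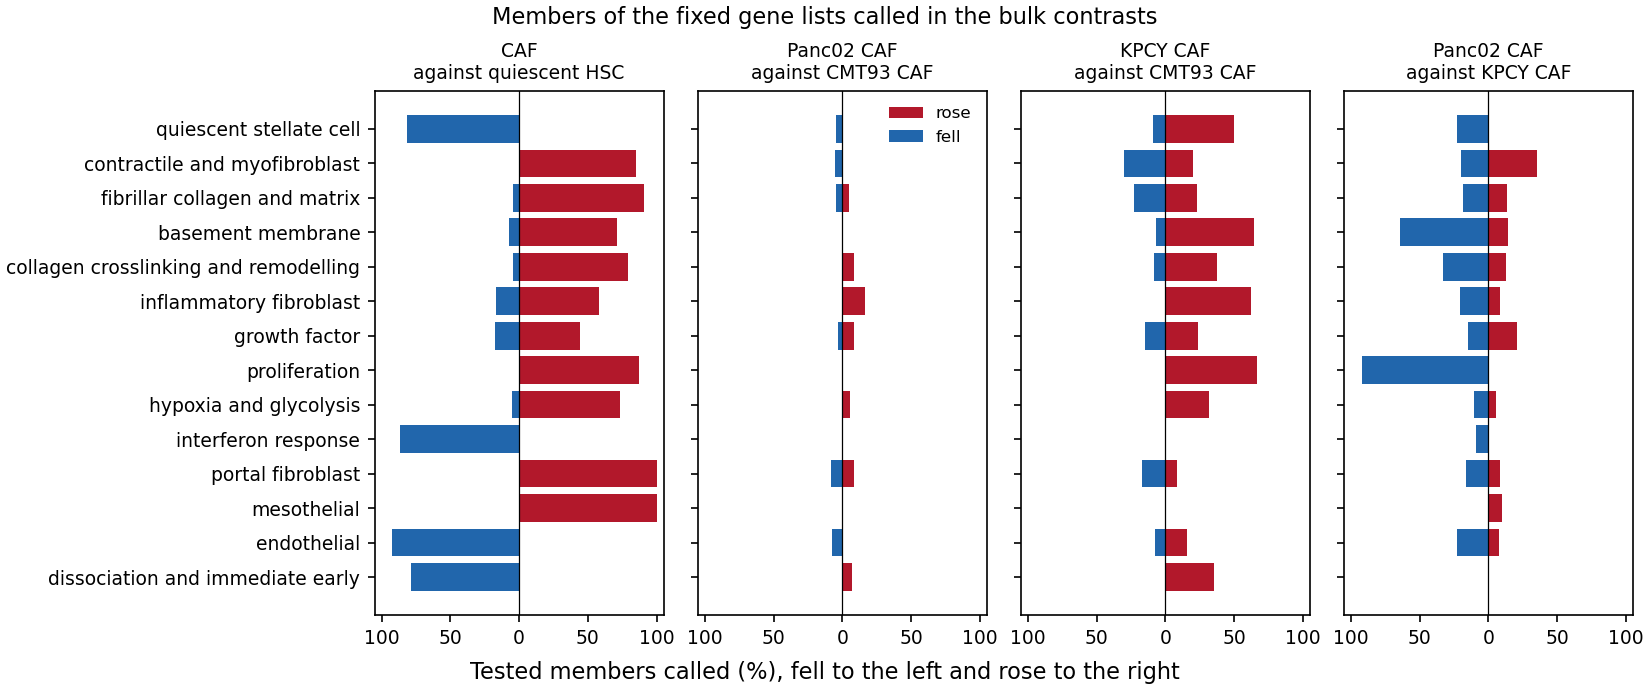
Share of tested members of 14 of the fixed gene lists that were called in each bulk comparison, with genes that fell to the left and genes that rose to the right. Of 22 quiescent stellate cell genes, 18 fell in CAF against HSC, and 11 rose and 2 fell in KPCY against CMT93 CAF.

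Comparing CAF between tumour lines asked whether the stellate-derived fibroblasts depend on the tumour that made the metastasis. Panc02 and CMT93 CAF were the closest pair. Saa3, an acute-phase protein gene, was 526 TPM in Panc02 and 39.6 TPM in CMT93 (log2 fold change 3.56 ± 0.38, adjusted p = 0.00527). Nppc (a natriuretic peptide), Aqp5 (a water channel), Chl1, Dmkn, Rarres1, A2m, Car12, Arc and Gdpd2 were also higher in Panc02, by 3.51 to 2.79 on the log2 scale. Of these 10 genes only Nppc kept its call without CMT93 library 2, where adjusted p was 0.0733 for Saa3 and Chl1, 0.0993 for Aqp5, 0.256 for Dmkn, 0.160 for Rarres1, 0.0944 for A2m, 0.0918 for Car12, 0.142 for Arc and 0.105 for Gdpd2. Aqp5 (0.105), Dmkn (0.158), Rarres1 (0.0921), A2m (0.0921), Car12 (0.0513) and Gdpd2 (0.0957) also lost it without CMT93 library 1, and Arc (0.0524) without Panc02 library 1. Saa3 (Panc02 cluster 17) and Dmkn (Panc02 cluster 9), both also in CMT93 cluster 11, were among the leading genes of mesothelial-like single-cell clusters. Aqp5 was among the leading genes of the unnamed Panc02 cluster 22, which had no fibroblast marker on. Whether mesothelial cells or cells of that cluster were among the sorted CAF was not tested. Thy1, a surface glycoprotein of portal fibroblasts, was 244 TPM in Panc02 and 1106 TPM in CMT93 (-2.17 ± 0.16, adjusted p = 0.000865). The homeobox gene Meox1 fell by 2.05 ± 0.23, and Lhfpl3, Chil3 and Arg1 fell by 2.96, 2.81 and 2.17. These 4 calls were lost without CMT93 library 2 (adjusted p = 0.0733 for Meox1, 0.0629 for Lhfpl3, 0.171 for Chil3 and 0.165 for Arg1), that of Arg1 also without CMT93 library 1 (0.0617) and that of Chil3 without Panc02 library 1 (0.0548). The pancreatic chymotrypsinogen gene Ctrb1 was lower in Panc02 as well (0.433 against 12.1 TPM, -3.13 ± 0.35, adjusted p = 0.00527). Of the lowest 10, 4 were antigen receptor segments listed at 0 in all Panc02 libraries, with CMT93 values of 16.7 and 23.7 TPM for Igkv6-25, 8.46 and 17.3 TPM for Ighv9-3, 10.1 and 13.6 TPM for Ighv1-22 and 15.4 and 5.38 TPM for Trbj2-7. In a fit of these 5 libraries alone the calls of Ctrb1 (adjusted p = 0.0541), Trbj2-7 (0.0569), Saa3 (0.0564), Aqp5, Dmkn, Rarres1, A2m, Car12, Arc, Gdpd2, Meox1, Lhfpl3, Chil3 and Arg1 were lost (adjusted p from 0.0532 to 0.151). With no filter those of Aqp5, Dmkn, Rarres1, A2m, Arc, Gdpd2, Chil3 and Arg1 were lost (0.0532 to 0.122), Dmkn also lost its call without trend (0.0588) and with the robust fit (0.0699), and Chil3 at a pseudocount of 0.1 (0.130).

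Of the study mediators, only Timp1 passed between Panc02 and CMT93 (0.74 ± 0.14, adjusted p = 0.0359), and its call was lost without any single library of either group, with adjusted p from 0.0563 to 0.249, as well as with no filter (0.0918), quantile scaling (0.0662), no trend (0.0662) and in the 2-group fit (0.132). Type I collagen did not differ detectably, with Col1a1 at 0.12 ± 0.15 (adjusted p = 0.740) and Col1a2 at 0.11 ± 0.15 (adjusted p = 0.753). Has2 averaged 45.7 TPM in Panc02 and 15.7 TPM in CMT93 (1.40 ± 0.33, adjusted p = 0.0700), and passed under median-ratio scaling (adjusted p = 0.0419). Hgf was at 0.79 ± 0.33 (adjusted p = 0.269), Lrat at 0.40 ± 0.50 (adjusted p = 0.737), Acta2 at -0.25 ± 0.16 (adjusted p = 0.480), Cd44 at 0.31 ± 0.12 (adjusted p = 0.228) and Cxcl12 at 0.67 ± 0.43 (adjusted p = 0.486, but 0.00947 without Panc02 library 2). Il6 was 1.97 ± 0.64 (adjusted p = 0.169), with CMT93 libraries at 55.2 and 8.07 TPM, and passed without CMT93 library 1 (adjusted p = 0.0177).

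Inflammatory fibroblast genes rose in 4 of 24 cases in Panc02 against CMT93 and none fell, and 12 rose adjusted over the list alone (median 0.94, camera adjusted p = 7.05e-10, adjusted p = 0.217 with an estimated correlation). The 4 were Lcn2 (2.38 ± 0.19), Saa3, Svep1 (0.88 ± 0.13) and Il33 (1.28 ± 0.24). Immediate early genes moved with them, with 1 of 14 up (Hspa1b, 2.54 ± 0.52) and 10 up adjusted over the list alone (median 1.22, camera adjusted p = 3.09e-08, adjusted p = 0.436 with an estimated correlation). Growth factor genes rose in 3 of 34 cases and fell in 1, and in 8 and 2 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.217 with an estimated correlation), with the epidermal growth factor family ligand Ereg at 1.39 ± 0.21 and Tgfb3 at -0.94 ± 0.16. In the hypoxia list 1 of 19 rose (Egln3, 2.05 ± 0.34), and 2 adjusted over the list alone (camera adjusted p = 2.40e-06, adjusted p = 0.217 with an estimated correlation). The mesothelial list had 0 of 10 members past the test over all genes and 6 up adjusted over the list alone (median 1.24, camera adjusted p = 4.00e-06, adjusted p = 0.339 with an estimated correlation). YAP targets rose in 3 of 15 cases, among them Ccn1 (1.11 ± 0.15), smooth muscle genes in 3 of 10 and hyaluronan genes in 1 of 14 (Ugdh, 0.67 ± 0.13), with camera adjusted p = 0.0173, 0.0347 and 0.0319 and adjusted p = 0.657, 0.540 and 0.236 with an estimated correlation. Adjusted over the list alone, 4, 4 and 3 of these rose, and 1 smooth muscle gene fell.

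Of the other camera calls in Panc02 against CMT93, hepatocyte (1 of 17 up), platelet (1 of 3 up), erythroid (0 of 5 up) and mitochondrially encoded genes (0 of 13 up) had camera adjusted p = 0.0319, 0.0159, 0.0173 and 0.00708, and adjusted p = 0.657, 0.217, 0.479 and 0.657 with an estimated correlation. Interferon genes and dendritic cell genes leaned lower, with 0 of 22 and 0 of 7 past the test (camera adjusted p = 0.00656 and 0.0173, adjusted p = 0.540 and 0.217 with an estimated correlation), and with 3 and 2 down adjusted over the list alone. Adjusted in that way 3 hepatocyte and 2 platelet genes rose. No call was made for contractile (1 of 20 down, Thy1), fibrillar matrix (1 up and 1 down of 22), quiescent stellate cell (1 of 22 down, Rbp1) or proliferation genes (0 of 24, the lowest adjusted p being 0.144 for Rrm2).

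Across all genes 177 were higher and 152 lower in Panc02 than in CMT93 CAF, 329 in total, against 2388 at an unadjusted p under 0.05 where chance gives 710.9. The count was 188 without Panc02 library 1, 125 without CMT93 library 1 and 29 without CMT93 library 2 (24 of them among the 329), and 30 in a fit of these 5 libraries alone. More genes were lower than higher with no filter (94 and 45), without Panc02 library 2 (204 and 180), without CMT93 library 2 (23 and 6) and in the fit of 5 libraries (18 and 12). Without immunoglobulin, T-cell receptor and pancreatic acinar genes, an alternative chosen after seeing the data, it was 303.

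KPCY CAF differed more from CMT93 CAF. Il11, an interleukin 6 family cytokine, stood at 82.3 TPM in KPCY and 4.24 TPM in CMT93 (3.97 ± 0.35, adjusted p = 0.000508). The orphan nuclear receptor genes Nr4a2 and Nr4a3, Syt5, Plvap, which was among the leading genes of stellate-cell-like single-cell clusters, and 5 genes that were high in quiescent HSC (Colec10, Angptl6, Tmem56, Fcna and Nrxn1) rose by 4.19 to 3.31 on the log2 scale. The calls of Colec10, Angptl6, Fcna and Plvap were lost without any single library of either group, with adjusted p from 0.0615 to 0.149, 0.0932 to 0.242, 0.0702 to 0.210 and 0.0554 to 0.155. Angptl6 also lost its call under both other scalings (adjusted p = 0.0547 and 0.0625) and both other pseudocounts (0.0615 and 0.0532). Tmem56 lost its call without CMT93 library 1 (adjusted p = 0.0648) or 2 (0.0934), and Nr4a3 without CMT93 library 2 (0.111), KPCY library 1 (0.0611) or KPCY library 2 (0.0726). With no filter and with the robust fit Colec10 (0.0831 and 0.0669), Angptl6 (0.131 and 0.107), Plvap (0.0760 and 0.0612), Nr4a3 (0.0794 and 0.0638) and Fcna (0.0930 and 0.0759) lost their calls, and Angptl6 also without trend (0.0708). The largest falls were of Wnt16, a Wnt ligand (0.239 against 66.0 TPM, -5.74 ± 0.28, adjusted p = 2.38e-05), Cyp26a1, which degrades retinoic acid (-5.71 ± 0.35, adjusted p = 0.000108), and Notum, a secreted inactivator of Wnt proteins (1.27 against 98.8 TPM, -5.49 ± 0.27, adjusted p = 2.38e-05). Notum lies on chromosome 11 at 120653788 to 120661175 (GRCm38). The Wnt-responsive transcription factor gene Lef1 (-3.88 ± 0.39, adjusted p = 0.000893), the retinol uptake receptor gene Stra6 (-3.91 ± 0.21, adjusted p = 4.70e-05), the protease gene Prss35 (-4.10 ± 0.19, adjusted p = 2.38e-05) and Syt13 (-4.15 ± 0.18, adjusted p = 2.13e-05) fell too. Antigen receptor segments made up the rest, with Ighj1 listed at 0 in all KPCY libraries and at 9.92 and 71.0 TPM in CMT93, Ighj2 at -4.17 ± 1.15 and Igkv6-25 at -4.09 ± 0.33. The call of Ighj2 was lost without CMT93 library 1 (adjusted p = 0.124), CMT93 library 2 (0.218), KPCY library 2 (0.106) or KPCY library 3 (0.106), with no filter (0.112), without trend (0.0586) and with the robust fit (0.0916).

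Hgf was 205 TPM in KPCY and 36.3 TPM in CMT93 CAF (2.45 ± 0.33, adjusted p = 0.00264). Hgf was also high in quiescent HSC (1268 TPM). Whether sorted KPCY cells closer to the quiescent state, a question left open below, account for its higher value was not tested. Has2 rose by 1.20 ± 0.33 (adjusted p = 0.0359), a call lost without any single library (adjusted p from 0.0540 to 0.198), with no filter (0.0970) and without trend (0.0546). Timp1 rose by 1.67 ± 0.14 (adjusted p = 0.000455). Cd44 rose by 0.53 ± 0.12 (adjusted p = 0.0175), a call lost without CMT93 library 1 (adjusted p = 0.105), CMT93 library 2 (0.0877) or KPCY library 2 (0.0540). Il6 rose by 3.15 ± 0.64 (adjusted p = 0.0132), a call lost without CMT93 library 2 (adjusted p = 0.0544) and with no filter (0.0509). Lrat rose by 2.12 ± 0.50 (adjusted p = 0.0224), a call lost without CMT93 library 1 (adjusted p = 0.130), CMT93 library 2 (0.119), KPCY library 2 (0.0681) or KPCY library 3 (0.0575) and with no filter (0.0733). Acta2 fell by 0.72 ± 0.16 (adjusted p = 0.0180), a call lost without CMT93 library 1 (adjusted p = 0.0732), CMT93 library 2 (0.124), KPCY library 2 (0.0522) or KPCY library 3 (0.0611) and with no filter (0.0503). Col1a1 (-0.32 ± 0.15, adjusted p = 0.172), Col1a2 (-0.38 ± 0.15, adjusted p = 0.110) and Cxcl12 (1.13 ± 0.43, adjusted p = 0.102) did not pass, but in the fit of these 2 groups alone Col1a2 (0.0459) and Cxcl12 (0.00426) did.

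Quiescent stellate cell genes rose in 11 of 22 cases in KPCY against CMT93 and fell in 2 (median 1.39, camera adjusted p = 0.00839, adjusted p = 0.749 with an estimated correlation), with Nrxn1 at 3.31 ± 0.50 and Rgs5 at 1.67 ± 0.30. Inflammatory fibroblast genes rose in 15 of 24 cases with none down (median 1.18, camera adjusted p = 4.92e-07, adjusted p = 0.493 with an estimated correlation), among them the eosinophil chemokine Ccl11 (3.16 ± 0.42) and Lcn2 (1.63 ± 0.19). Immediate early genes rose in 5 of 14 cases with none down, and in 13 adjusted over the list alone (median 1.41, camera adjusted p = 0.000218, adjusted p = 0.632 with an estimated correlation). Proliferation genes rose in 16 of 24 cases with none down (camera adjusted p = 4.68e-09, adjusted p = 0.632 with an estimated correlation), led by topoisomerase Top2a (1.39 ± 0.18). Basement membrane genes rose in 9 of 14 cases and fell in 1 (camera adjusted p = 0.00988, adjusted p = 0.493 with an estimated correlation), with Col15a1 at 1.95 ± 0.21 and Col4a5 at -1.74 ± 0.21. Class II genes fell in 5 of 10 cases with none up (camera adjusted p = 0.00343, adjusted p = 0.632 with an estimated correlation), for example H2-Eb1 (-1.20 ± 0.26). Contractile genes were split, 4 up and 6 down of 20 (camera adjusted p = 0.0396, adjusted p = 0.632 with an estimated correlation), with Myl9 at -1.26 ± 0.18 and Fap at 1.15 ± 0.17. Crosslinking genes (9 up and 2 down of 24), hypoxia genes (6 up of 19), smooth muscle genes (6 up and 1 down of 10) and platelet genes (2 up of 3) had camera adjusted p = 0.0396, 0.0139, 0.0317 and 0.0353, and adjusted p = 0.632, 0.632, 0.632 and 0.493 with an estimated correlation. Adjusted over the list alone, the counts up and down were 15 and 2 for quiescent stellate cells, 16 and 0 for inflammatory, 23 and 0 for proliferation, 9 and 2 for basement membrane, 0 and 8 for class II, 5 and 9 for contractile, 11 and 3 for crosslinking, 7 and 0 for hypoxia and 6 and 3 for smooth muscle genes. Growth factor genes had no call as a list (8 up and 5 down of 34, camera adjusted p = 0.491), with Wnt2 at -3.81 ± 0.23 and Tgfb1 at 1.13 ± 0.15, and endothelial genes had none either (2 up and 1 down of 13, camera adjusted p = 0.133), with Flt1 at 1.72 ± 0.20.

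In total 1529 genes were higher and 1053 lower in KPCY than in CMT93 CAF. The split was 1209 up and 1487 down under quantile scaling, and the total fell to 1260, 1477 and 1355 without KPCY library 1, 2 or 3 and to 892 and 481 without CMT93 library 1 or 2.

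Between the pancreatic lines, Cyp26a1, Wnt16 and Notum again stood apart, while 2 of 14 retinoid and lipid droplet genes rose and 2 fell (camera adjusted p = 0.322). Panc02 CAF held 91.4 TPM of Cyp26a1 against 0.394 TPM in KPCY (6.07 ± 0.31, adjusted p = 2.89e-05), and Wnt16 (5.07 ± 0.25), Ndnf, Notum (4.93 ± 0.24), Tnfrsf19 (4.36 ± 0.26), Aqp5, Pnoc, Prss35, Slc38a4 and Igfbp2 were higher in Panc02 too. Il11 was 6.14 TPM in Panc02 and 82.3 TPM in KPCY (-3.57 ± 0.31, adjusted p = 0.000424), and Megf11, Syt5, Sema7a, Itgb3, Mtcl1, Ngfr, Col15a1 and Mcam fell by 3.28 to 2.49. Tff1, a trefoil peptide of mucous epithelium, fell by 4.75 ± 1.17 (adjusted p = 0.0326), with KPCY libraries at 23.6, 237 and 3.47 TPM, a call lost without Panc02 library 1 (adjusted p = 0.0860), 2 (0.0542) or 3 (0.0728) or KPCY library 1 (0.0854), with no filter (0.101), without trend (0.0504), with the robust fit (0.0736) and in the 2-group fit (0.0576). Hgf fell by 1.66 ± 0.29 (adjusted p = 0.00915) and Timp1 by 0.93 ± 0.13 (adjusted p = 0.00325). Lrat fell by 1.72 ± 0.45 (adjusted p = 0.0377), a call lost under both other scalings (adjusted p = 0.0561 and 0.0570), with no filter (0.112), without trend (0.0603), with the robust fit (0.0746), in the 2-group fit (0.0694) and without 5 of the 6 libraries, with adjusted p = 0.122 and 0.0609 without Panc02 library 1 or 2 and 0.0672, 0.119 and 0.0941 without KPCY library 1, 2 or 3. Col1a2 rose by 0.49 ± 0.13 (adjusted p = 0.0435), a call lost under quantile scaling (adjusted p = 0.122), with no filter (0.174), in the 2-group fit (0.0691) and without 5 of the 6 libraries, with adjusted p = 0.0714 and 0.0592 without Panc02 library 1 or 3 and 0.124, 0.134 and 0.128 without KPCY library 1, 2 or 3. Col1a1 (0.44 ± 0.14, adjusted p = 0.0643), Has2 (0.20 ± 0.29, adjusted p = 0.679), Acta2 (0.47 ± 0.14, adjusted p = 0.0601), Cd44 (-0.23 ± 0.10, adjusted p = 0.182), Il6 (-1.18 ± 0.57, adjusted p = 0.198) and Cxcl12 (-0.46 ± 0.39, adjusted p = 0.456) did not pass. Col1a1 passed at the 5 TPM filter (adjusted p = 0.0452) and with the robust fit (0.0294), Acta2 with the robust fit (0.0482) and Il6 in the 2-group fit (0.0411).

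Proliferation genes fell in 22 of 24 cases in Panc02 against KPCY with none up (median -0.85, camera adjusted p = 9.02e-12, adjusted p = 0.640 with an estimated correlation), including Mki67 (-1.24 ± 0.18) and Ccnb1 (-1.08 ± 0.15). Basement membrane genes fell in 9 of 14 cases and rose in 2, and quiescent stellate cell genes fell in 5 of 22 with none up (camera adjusted p = 0.00441 and 0.00196, both with adjusted p = 0.640 with an estimated correlation), among them Col4a1 (-1.37 ± 0.14), Rgs5 (-1.57 ± 0.26) and Ngfr (-2.58 ± 0.45). Class II genes rose in 5 of 10 cases and fell in 1, and mesothelial genes rose in 1 of 10 (camera adjusted p = 0.00337 for each, adjusted p = 0.640 with an estimated correlation for each). Adjusted over the list alone, the counts up and down were 0 and 23 for proliferation, 2 and 10 for basement membrane, 1 and 11 for quiescent stellate cells, 8 and 1 for class II and 5 and 0 for mesothelial genes. No call was made for contractile (7 up and 4 down of 20, with Thy1 at -1.88 ± 0.14), fibrillar matrix (3 up and 4 down of 22), inflammatory (2 up and 5 down of 24) or growth factor genes (7 up and 5 down of 34, with Wnt2 at 3.53 ± 0.21 and Wnt4 at 1.90 ± 0.15).

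In total 744 genes were higher and 1141 lower in Panc02 than in KPCY CAF, a split that became 1030 and 769 under median-ratio scaling and 1040 and 813 under quantile scaling. The total was 909 without Panc02 library 1 and 771, 1029 and 949 without KPCY library 1, 2 or 3. Of the genes lower in KPCY against CMT93 (1053) and against Panc02 (744), 440 were shared, and of those higher in KPCY (1529 and 1141), 694 were shared. Independent lists would share 55.1 and 122.7, but part of the excess may come from the shared KPCY libraries. In 20 simulations with no effect the highest overlap was 0, which says little because groups without an effect give few calls to overlap.

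Single-cell sequencing asked which cells of the metastasis-bearing liver express these mediators and their receptors. With 1 library per model there was no test, and intervals cover counting error only. The tumour models are those of the sample titles, since the sample descriptions name cholangiocarcinoma models instead. Clusters were named from markers fixed in advance, while the thresholds for naming were set after seeing the data. After filtering, 4734 Panc02 and 5902 CMT93 cells fell into 27 and 24 clusters. Fibroblast-like cells made up 56.3% of Panc02 cells (95% Clopper-Pearson interval 54.8 to 57.7%) and 52.2% of CMT93 cells (51.0 to 53.5%), shares set largely by the sort, which mixed Col1a1-GFP+ cells with unsorted live cells. The order of the libraries was not stable, because under all 6 other filters and resolutions the share was higher in CMT93 (57.5% to 65.3%) than in Panc02 (56.1% to 60.1%). Mesothelial-like cells were 14.0% and 5.96%, endothelial-like cells 3.06% and 14.5%, macrophage/monocyte-like cells 10.3% and 6.37%, T/NK-like cells 5.01% and 2.69%, dendritic-like cells 4.31% and 1.36%, smooth muscle/pericyte-like cells 1.80% and 1.61%, epithelial-like cells 0.739% and 1.05%, and B/plasma-like cells 0.887% and 0.661%. Hepatocyte-like cells were 0.296% of Panc02 cells. The naming thresholds left 3.36% of Panc02 cells (clusters 22 and 26) and 13.6% of CMT93 cells (clusters 2, 7 and 12) unnamed, of which CMT93 cluster 2 (679 cells) carried all 9 fibroblast markers.

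Within fibroblast-like cells, stellate-cell-like cells were 34.5% in Panc02 (clusters 2 and 3) and 23.8% in CMT93 (cluster 13). Myofibroblast-like cells were 22.8% (clusters 8 and 10) and 41.4% (clusters 1, 3, 5 and 14), and portal-fibroblast-like cells 23.9% (clusters 1, 12, 13 and 20) and 28.5% (clusters 8, 9 and 19). For portal-fibroblast-like cells the order of the libraries turned under 5 of the 6 other filters and resolutions. The portal-fibroblast-like class did not cover the same clusters in the 2 libraries, since CMT93 cluster 9 (437 of its 879 cells) shared 6 of its 10 leading genes (Vegfd, Dpep1, Fbln5, Tnnt2, C7 and Sfrp1) with Panc02 cluster 4 (388 cells), which had no sub-class. The remaining 18.8% and 6.29% (Panc02 clusters 4 and 21, CMT93 cluster 4) were given no sub-class by a rule also set after seeing the data. The unnamed CMT93 cluster 2 (679 cells) is in none of these shares. It had 5 myofibroblast, 4 portal-fibroblast and 1 stellate-cell markers on. Median UMIs per cell were 7757 and 6925 in stellate-cell-like and 22644 and 17566 in myofibroblast-like cells.

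Hgf sat in another fibroblast sub-class than Has2 and Col1a1. Hgf reached 661 CPM (UMIs of the gene scaled to the same total per class; 95% Poisson interval 643 to 680) in stellate-cell-like cells of Panc02 and 442 (425 to 461) in those of CMT93, against 41.8 and 47.9 CPM in myofibroblast-like and 19.5 and 37.4 CPM in portal-fibroblast-like cells. Endothelial-like cells held 138 and 84.8 CPM of Hgf. The log2 ratio of Hgf in stellate-cell-like over myofibroblast-like cells was 3.95 (3.80 to 4.11) in Panc02 and 3.18 (3.04 to 3.32) in CMT93. Cells with an Hgf UMI were 94.7% and 90.7% of stellate-cell-like cells (69.4% and 56.9% after thinning to 2000 UMIs per cell), and 2.53% and 1.26% of T/NK-like cells (0.448% and 1.41% thinned), whose median depths were 3849 and 2978 UMIs.

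Has2 lay with type I collagen. It was at 30.7 CPM (27.9 to 33.7) and 49.9 CPM (47.1 to 52.8) in myofibroblast-like cells of Panc02 and CMT93 and at 8.77 and 11.2 CPM in portal-fibroblast-like cells. In stellate-cell-like cells Has2 was at 0.267 CPM in Panc02 and had no UMI in the 735 cells of CMT93, which allows up to 0.685 CPM. Cells with a Has2 UMI were 27.5% and 30.4% of myofibroblast-like cells (5.48% and 8.25% thinned) and 0 of 237 and 0 of 159 T/NK-like cells. Col1a1 reached 7950 and 7782 CPM in myofibroblast-like, 3445 and 4154 CPM in portal-fibroblast-like and 549 and 403 CPM in stellate-cell-like cells, against 61.3 and 150.1 CPM in T/NK-like cells. Has1, another hyaluronan synthase gene, was instead highest in portal-fibroblast-like (251 and 125 CPM) and mesothelial-like cells (160.3 and 224 CPM). Cxcl12 was highest in stellate-cell-like cells (4435 and 3720 CPM), and Il6 (81.8 and 222 CPM) and Igf1 (866 and 405 CPM) in portal-fibroblast-like cells.

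The Hgf receptor gene Met (chromosome 6, 17463800 to 17573980, GRCm38) was at 93.6 CPM (87.6 to 99.9) and 114 CPM (103 to 126) in mesothelial-like cells and at 56.9 CPM (32.5 to 92.3) and 47.4 CPM (37.3 to 59.5) in epithelial-like cells of Panc02 and CMT93. In all fibroblast-like cells Met was at 0.634 and 1.01 CPM. Met UMIs were found in 66.4% and 60.8% of mesothelial-like cells (20.9% and 19.4% thinned) and in none of the T/NK-like cells. Cd44 was highest in macrophage/monocyte-like cells (498 and 693 CPM), with 60.4 and 159 CPM in epithelial-like, 91.2 and 102 CPM in myofibroblast-like and 30.9 and 24.3 CPM in stellate-cell-like cells. The collagen receptor gene Ddr1 was highest in epithelial-like cells of Panc02 (159.9 CPM) and in mesothelial-like cells of CMT93 (202 CPM), whereas Ddr2 was highest in portal-fibroblast-like cells (211 and 221 CPM). The Panc02 epithelial-like values come from 35 cells (cluster 25), and the unnamed Panc02 cluster 22 (141 cells) is in none of these values. The leading genes of Panc02 cluster 25 (such as Tm4sf4, Epcam and Spp1) included none of those of CMT93 cluster 16 (such as Clps, Agr2 and Gkn1). The epithelial-like values of the libraries may thus come from different cells. Which clusters hold tumour cells was not tested.

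**Figure D3:**
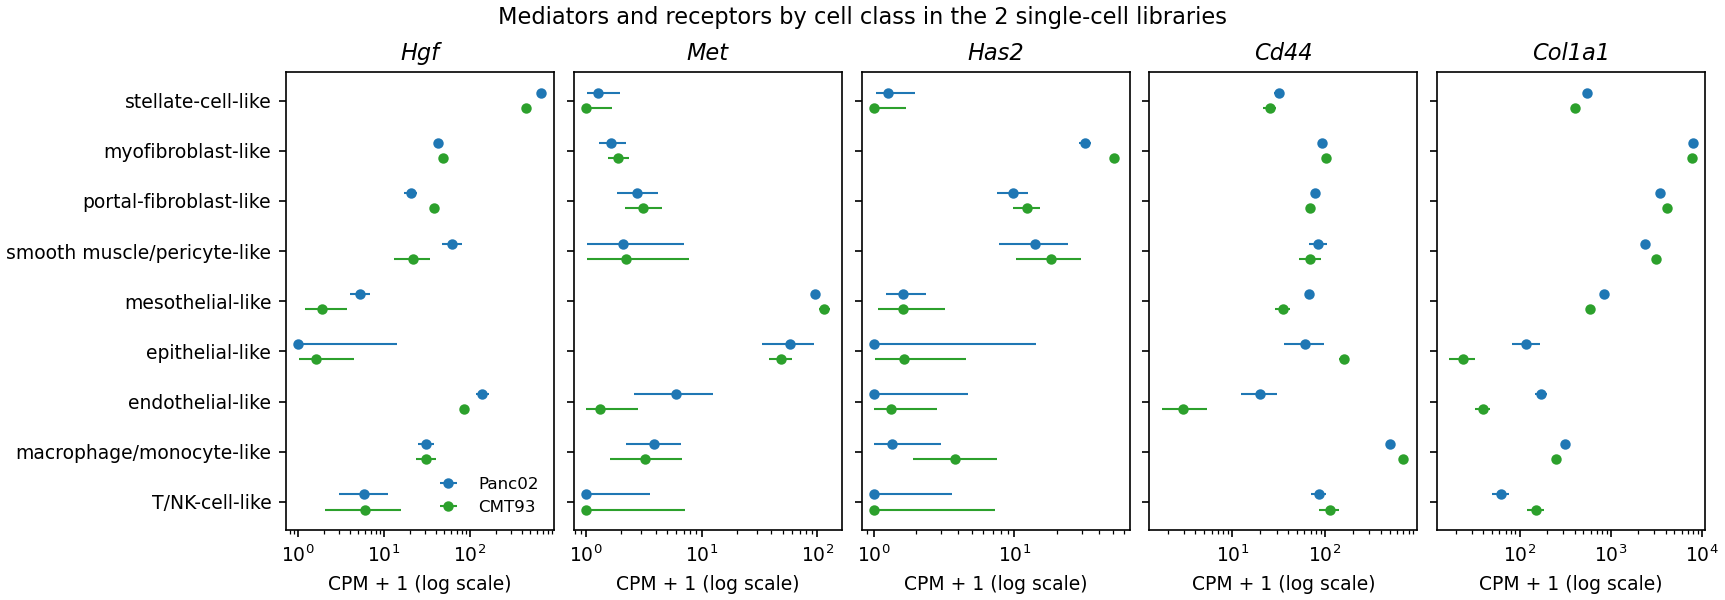
CPM of Hgf, Met, Has2, Cd44 and Col1a1 in 9 cell classes of the Panc02 and CMT93 single-cell libraries on a log axis of CPM + 1, with exact Poisson intervals and a CPM of 0 drawn at 1. Hgf stood highest in stellate-cell-like cells (661 and 442 CPM) and Has2 in myofibroblast-like cells (30.7 and 49.9 CPM).

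Between the 2 single-cell libraries, fibroblast-like cells of Panc02 held more Mfap5 (252 against 31.5 CPM, log2 ratio 2.96), Thbs4 (2.69), Chl1 (2.06), Penk, Spon2, Slit3, Ifi205, Tppp3 and Ly6a (586 against 207 CPM). Ccnb1ip1, at 67.3 against 1.80 CPM, had the highest ratio (4.61). Tppp3 (-1.36) and Ifi205 (-0.05) were not higher within stellate-cell-like cells, nor was Ifi205 within myofibroblast-like cells (-0.19). Panc02 fibroblast-like cells held less of Cxcl2 (-3.07), Hbegf (-2.73), Rgs16 (-2.48), Atf3 (-2.18), Nme2, Il6 (20.1 against 85.4 CPM, -2.03), Dnajb1, Gadd45b, Ppp1r15a and Cxcl1 (-1.99). Among these Atf3, Dnajb1, Gadd45b and Ppp1r15a are stress-response genes. Hgf was 190 CPM (185 to 195) in Panc02 and 111 CPM (108 to 114) in CMT93, a log2 ratio of 0.77 that was -0.19 within myofibroblast-like and -0.91 within portal-fibroblast-like cells. Has2 was 15.5 and 33.8 CPM (-1.07). Its ratio of 0.34 within stellate-cell-like cells rested on almost no UMIs, with none in CMT93, so its sign carries no weight. Col1a1 was 4699 and 6009 CPM (-0.35, but 0.45 within stellate-cell-like and 0.03 within myofibroblast-like cells). The ratios of Col1a2 (-0.11), Acta2 (-0.34), Timp1 (0.30), Cd44 (-0.13), Lrat (0.45) and Cxcl12 (0.61) were smaller than 1 in size in the pooled cells. Within portal-fibroblast-like cells Lrat (-3.35), Acta2 (-1.56) and Cxcl12 (-1.12) passed that size and Cd44 changed sign (0.18). Within stellate-cell-like cells Col1a2 (0.39), Acta2 (0.59), Cd44 (0.33) and Lrat (-0.06) changed sign, as did Col1a2 (0.24), Acta2 (0.10) and Lrat (-0.07) within myofibroblast-like cells.

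The median log2 ratio of quiescent stellate cell genes in Panc02 over CMT93 fibroblast-like cells was 0.32, at percentile 100 among 10000 matched random lists, with 17 of 21 genes higher. It was -0.33 within myofibroblast-like and -1.05 within portal-fibroblast-like cells. The list holds all the markers that name the stellate-cell-like sub-class, whose share was larger in Panc02 (34.5% against 23.8%), so the pooled median may reflect that share. Random lists were drawn gene by gene, so a list of co-expressed genes can reach an extreme percentile from cell shares alone, here and below. Interferon (0.53, 20 of 21 higher), hypoxia (0.47, 16 of 18), class II (1.14, 6 of 7), portal fibroblast (0.60, 10 of 12) and inflammatory genes (0.41, 16 of 24) also lay at percentile 100. Crosslinking genes were at 0.20 (percentile 99.3) and mitochondrially encoded genes at 0.43 (percentile 99.96). Immediate early genes were lower in Panc02 (-0.89, 14 of 14 lower, percentile 0), as were growth factor genes (-0.24, 18 of 30, percentile 0), proliferation genes (-0.18, 19 of 24, percentile 0.07), contractile genes (-0.17, 13 of 19, percentile 1.59) and YAP targets (-0.17, 10 of 15, percentile 1.09). Within sub-classes proliferation genes reversed, to 0.28 in myofibroblast-like and 0.74 in portal-fibroblast-like cells. Fibrillar matrix (0.00), basement membrane (0.01) and hyaluronan genes (0.09) lay between percentiles 51.3 and 72.0.

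The bulk and single-cell contrasts of Panc02 with CMT93 were then set side by side. Of the 329 genes called in bulk, 305 were measured in fibroblast-like cells and 238 had the same sign there (78.0%, 95% interval 73.0 to 82.6%), 126 of 171 that rose and 112 of 134 that fell. Across these genes, which are not independent replicates, Pearson's r was 0.593 and Spearman's rho 0.564. Over all 10154 genes measured in both, 54.7% had the same sign (r = 0.152, rho = 0.160). Hspa1b, a heat shock protein gene called in bulk (2.54), had a single-cell ratio of -0.80, and the median of all immediate early genes was 1.22 in bulk and -0.89 in single cells. Medians also had opposite signs for growth factors (0.35 in bulk and -0.24 in single cells), YAP targets (0.15 and -0.17), interferon response genes (-0.22 and 0.53) and portal fibroblast genes (-0.13 and 0.60). The same held for antigen presentation class II (-0.15 and 1.14), hepatocyte (0.30 and -0.28), platelet (1.00 and -0.33), basement membrane (-0.14 and 0.01) and endothelial genes (-0.22 and 0.01). Single genes of opposite sign included Has2 (1.40 and -1.07) and Il6 (1.97 and -2.03), neither called in bulk. The bulk CAF were sorted for both reporters and the single-cell suspension took an added trypsin digestion, so the contrasts compare different sorts and preparations.

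**Figure D4:**
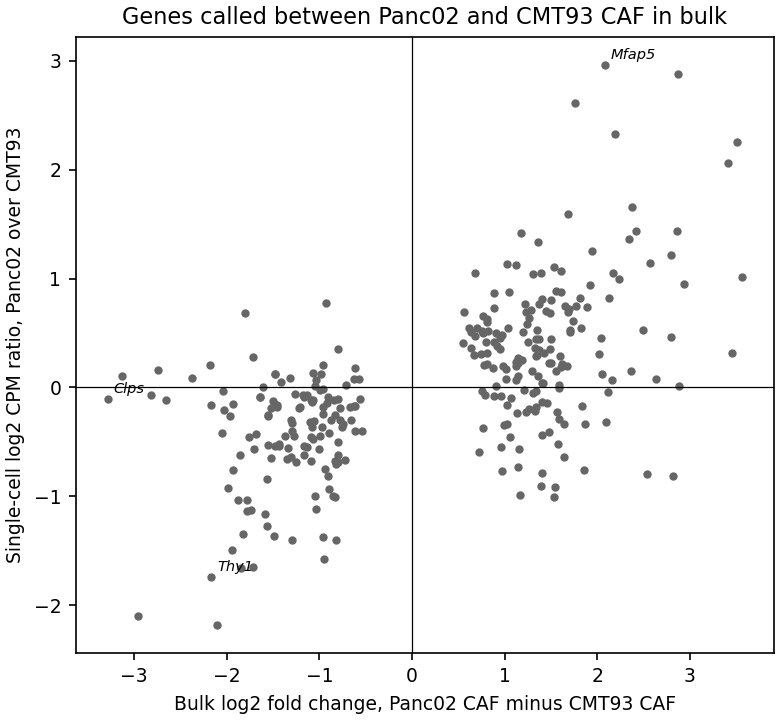
Bulk log2 fold change (x axis) against single-cell log2 CPM ratio in fibroblast-like cells (y axis), Panc02 over CMT93, for the 305 measured genes called in bulk, with 1 point per gene. Of these, 238 lie in the quadrants of equal sign.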

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

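All tests of explanations in this part, except the acinar test, were chosen after the result they concern was seen.

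Mcam (chromosome 9, 44134469 to 44142727, GRCm38), which encodes a cell adhesion molecule of pericytes, stood out because its effect against HSC differed between tumour models. It was -1.44 in Panc02 CAF and 1.06 in KPCY CAF, a difference of -2.49 (limma, adjusted p = 5.56e-05). Only the named genes of each comparison were searched. Mcam had been named for this same difference, so the adjusted p is not separate evidence. No group had 4 or more libraries, so single libraries were not tested as outliers.

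CMT93 CAF libraries held acinar and antigen receptor transcripts. Of 20 genes specific to the epithelial-like cells of the CMT93 single-cell library, 8 were higher in both CMT93 bulk libraries than in all 6 Panc02 and KPCY libraries, where chance gives 1 in 28 for each gene, while Gkn2 (41.5 TPM), Gkn1 (8.99), Mucl3 (7.14) and Cxcl17 (3.11) were highest in a Panc02 or KPCY library. This lay between the 10 set for tumour RNA carried into the sort and the 3 set against it, so the question stays open (a first run on tested genes only had covered 9 of the 20, with 3 higher). CMT93 tumour cells are an unlikely source of the 17 listed acinar transcripts such as Ctrb1, whose median CPM in 62 epithelial-like cells was 0 (highest 3.79, Sycn), but Clps, a pancreatic gene left off that list, reached 753 CPM there and 9.54 and 8.05 TPM in CMT93 bulk, so its source stays open. No biological explanation was tested.

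Quiescent stellate cell genes leaned higher in KPCY CAF, with 11 of 22 up and 2 down against CMT93 and 5 of 22 past the test against Panc02 (adjusted p = 0.749 and 0.640 with an estimated correlation). Of 27 genes at least 20 times higher in HSC than in the mean of the 3 CAF groups, 85.2% had their highest CAF mean in KPCY, 11.1% in Panc02 and 3.70% in CMT93, under the 90% set for sorted cells closer to the quiescent state (a first selection on low Panc02 and CMT93 values gave 90% but favoured KPCY), so that explanation stays open. Among the 40 genes of that first selection, the highest share of quiescent cells implied by a gene was 24.0%. Such a share would dilute other genes by 0.40 on the log2 scale. The 8 tested Wnt feedback targets had a median of -1.61 in KPCY over both comparisons (upper quartile -0.97). Dilution by cells as quiescent as the HSC library is thus an unlikely source of their fall. Cells that are only partly quiescent could make up a larger share, and for them the test does not decide. Fewer myofibroblast-like cells stay open, because the 19 genes of that sub-class went both ways (median 0.54 and quartiles -1.81 and 0.77 against CMT93). Cell cycle genes such as Top2a and Cdk1 were higher in KPCY, and Cdk1 was a leading gene of 2 clusters named myofibroblast-like (Panc02 10 and CMT93 14). The median thus mixes proliferation with the share of such cells and cannot decide. Acta2, Actg2, Aoc1, Cemip2, Cyp26a1, Fbn2, Prss35 and Ptger3 were lower in KPCY against both models, while Chst11 and Spp1 were higher.

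Cytokine genes as lists leaned higher in Panc02 and KPCY than in CMT93 CAF, together with immediate early genes. CMT93 library 2 carried much of this, with a mean log2(TPM + 1) of immediate early genes of 7.51 against 9.15 in CMT93 library 1, 9.62 in Panc02 and 9.71 in KPCY, and of primary-response cytokines of 3.33 against 4.96, 5.66 and 6.87. For the primary-response cytokines (Il6, Il11, Lif, Cxcl1, Cxcl2, Cxcl5, Ccl2 and Ccl7) the median single-cell ratio was -1.25, against 1.66 in bulk. In single cells the immediate early genes were also lower in Panc02. The other inflammatory genes had a median single-cell ratio of 0.74, and none of the 16 was lower. This split was made after the single-cell values were seen and follows their sign, with 8 of 8 cytokines lower and 0 of 16 others. The medians therefore restate the split and cannot decide whether isolation stress accounts for either part. KPCY had no single-cell library. The biological alternative, a difference between tumour models, remains possible for both parts.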

How the results depend on the processing

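All the tests within sub-classes and with the unnamed clusters were chosen after the result was seen. For CAF against HSC, named genes kept their direction and side of the threshold in all 240 leave-one-out and all 268 other values. Only CAF libraries were left out, so these values do not show how far the results depend on the single HSC library. Across comparisons, 631 of 720 leave-one-out values for named genes stayed the same, 87 lost the call and 2 gained it, and of 1040 values under other settings 989 stayed, 47 lost it and 4 gained it. In fits of 2 groups alone 69 of 90 stayed, 18 lost it and 3 gained it. Of 360 bulk list values 276 stayed, 67 lost the call and 15 gained it. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 6 in Panc02 against CMT93 and 8 in Panc02 against KPCY CAF. In CAF against HSC the direction reversed with fry for YAP targets (adjusted p = 0.0347) and retinoid genes (adjusted p = 0.0256).

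Counts of called genes for Panc02 against CMT93 CAF were 139 with no filter, 30 in a 2-group fit and 29 to 384 with a library left out. They were 481 to 1477 with a library left out for KPCY against CMT93, and 1217 with no filter and 771 to 2675 with a library left out for Panc02 against KPCY. Where an arm was left with 1 library, it was assumed to vary like the others. Fewer libraries explain part of the losses, and otherwise the cause was not tested.

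The fibroblast-like share of CMT93 cells was 65.3% and 57.5% at Leiden resolutions 0.5 and 2, 63.2% and 64.1% at 200 and 1000 genes per cell, 60.5% at 10% mitochondrial UMIs and 62.6% with no doublet removal. In Panc02 it was 60.1% at 1000 genes per cell. Of 118 shares 72 stayed the same and 46 moved. The main CMT93 share left out cluster 2, which carried all fibroblast markers but had more markers of another class among its leading genes. Counting that cluster as fibroblast-like would raise the main share. Whether its naming accounts for the higher shares at the other settings was not tested, nor was the cause of the other moves.

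The single-cell log2 ratio of Panc02 over CMT93 for Col1a1 was -0.34 without the 20 most abundant genes, -0.49 thinned, -0.52 as a per-cell mean, -0.45 with no doublet removal, -0.44 with the unnamed clusters and -0.27 in portal-fibroblast-like cells. Has2 was at -1.28 thinned, -1.31 as a per-cell mean, and -0.68 in myofibroblast-like and -0.32 in portal-fibroblast-like cells. Hgf was at 1.00 with no doublet removal, 0.97 with the unnamed clusters and 0.58 in stellate-cell-like cells. The Col1a1 ratio of stellate-cell-like over myofibroblast-like cells in Panc02 was -3.97 thinned and -3.95 as a per-cell mean. The Has2 ratio within stellate-cell-like cells rested on almost no UMIs, with none in CMT93, so its reversal carries no weight. Ratios reversed within stellate-cell-like cells for Acta2 (0.59), Cd44 (0.33), Col1a1 (0.45), Col1a2 (0.39), Has2 (0.34), Ifi205 (-0.0458), Lrat (-0.0622) and Tppp3 (-1.36). Within myofibroblast-like cells they reversed for Acta2 (0.10), Col1a1 (0.0308), Col1a2 (0.24), Hgf (-0.19), Ifi205 (-0.19), Lrat (-0.0659), and the proliferation (0.28) and quiescent stellate cell lists (-0.33). Within portal-fibroblast-like cells they reversed for Cd44 (0.18), Cxcl12 (-1.12), Hgf (-0.91), Lrat (-3.35), and the proliferation (0.74) and quiescent stellate cell lists (-1.05). The portal-fibroblast-like class includes CMT93 cluster 9 but not Panc02 cluster 4, which shares 6 of its 10 leading genes, so its ratios compare partly different cells. The shares of the sub-classes also differ between the libraries, and the cause of the reversals was not tested. Depth limits Has2 and Met, for which thinning to 2000 UMIs left most cells of the highest class without a UMI.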

Other observations

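The Wnt test below was set before its genes were examined, prompted by Notum, Lef1 and Axin2, and the test of other splits was set before its result.

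The hypothesis was that Wnt feedback targets as a group are lower in KPCY CAF than in CMT93 CAF. With Notum, Lef1 and Axin2 left out, 8 of 11 targets were tested and 4 fell (median -1.31, camera p = 4.33e-06, p = 0.0124 with an estimated correlation). Among them Nkd1, an inhibitor of Wnt signalling, was at -1.93, Apcdd1 at -2.33 and the transcription factor gene Tcf7 at -1.74. In Panc02 against KPCY CAF 6 of the targets rose (median 1.51, camera p = 3.11e-10, p = 0.00339 with an estimated correlation), while in Panc02 against CMT93 CAF Lgr5 rose (2.17), Apcdd1 fell (-1.13) and the list was not called (camera p = 0.625). Lower Wnt pathway output in KPCY CAF is 1 reading, but no protein was measured, and both comparisons share the KPCY libraries. Fewer cells of a state that expresses these genes is another, since Nkd2, 1 of the 8, was a leading gene of the myofibroblast-like CMT93 cluster 1. These readings were not told apart.

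The 6 Panc02 and KPCY libraries can be split into 3 and 3 in 10 ways. Only the real split, 1 of 10, called as many as 1885 genes, and the highest other split called 1. With 10 splits a share under 0.05 cannot be reached.

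In the Panc02 single-cell library the unnamed cluster 22 (141 cells, median 27022 UMIs) had 0 of 9 fibroblast markers on, and Aqp5, Stra6, Ptn, Tspan8, Wnt10a and Notum were among its 10 leading genes. Aqp5, Notum and Stra6 were also higher in Panc02 than in KPCY CAF in bulk, and whether such cells were among the sorted CAF was not tested. CMT93 CAF, which came from another tumour line, held 98.8 TPM of Notum and 24.6 TPM of Stra6, against 1.27 and 0.735 TPM in KPCY. Aqp5 was high only in Panc02 (41.0 TPM, against 2.25 in CMT93 and 0.958 in KPCY).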
